A study of Mus musculus with 6 samples.

How the data were processed

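RNA was measured by sequencing in 6 samples of mouse hippocampus, 3 that received a control virus and 3 that received a virus directed against SFRS8, the older name of Sfswap, which encodes a splicing regulator. Per the labels' protocols, 1.5 µg of total RNA per library was enriched for poly(A) RNA with oligo(dT) beads, fragmented, copied into cDNA with random primers and size-selected at about 350 bp. The protocol records no step that marks the strand, so it is not known whether reads of overlapping genes on opposite strands were kept apart. Per the submitters' processing notes, the genome build was mm10. The aligner and the counting program are not given in the sources used here.

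The authors deposited 1 table of FPKM values (fragments per kilobase of exon, scaled by the size of the library), with 30708 genes in rows, the 6 samples in columns, and a position and GO terms for each gene. The table gives values per gene and not per transcript, so the planned comparison of transcript shares was not possible. Of the gene identifiers, 30642 matched GENCODE release M21, and 93.4% of these had the same start and end there.

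Read depth was recovered from the FPKM values. Multiplying each value by the gene's summed exon length in GENCODE M21 gave whole multiples of a single step per sample, and this step gave a library total of 16622948 to 18097344 reads. Between 90.7% and 90.9% of the values above 0 lay within 0.01 reads of a whole number. All 6 values were whole for 28224 genes, which included 12274 of the 14013 genes tested. At these depths 1 read on a gene of 1 kb was worth 0.0553 to 0.0602 FPKM, and a value of 0 allows up to 3 reads, or 0.166 to 0.180 FPKM on such a gene. These floors cover counting error only.

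Genes with a mean of at least 1 FPKM over the 6 samples were tested. A linear model with the group as its only term was fitted to log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Every log2 fold change is knockdown minus control on the log2(FPKM + 1) scale, where the pseudocount of 1 understates the change of genes with low values. Values are given as mean ± SD over 3 samples, and fold values are ratios of the group means in FPKM. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples, which may be technical.

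Before the data were examined, 33 gene lists were fixed, covering splicing factors (SR proteins and their kinases, the core spliceosome, neuronal splicing regulators), synapses and channels, LTP and CREB signalling, immediate early genes, glia, immune cells, vessels, choroid plexus, hippocampal cell types, neighbouring brain regions, stress responses, ribosomal and respiratory genes, blood and sex-linked genes. Of these, 32 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. Each was also tested with camera at an estimated correlation and with fry, whose p-value asks whether the members move on balance one way without comparing them with other genes. Members were counted past the threshold over all genes tested, and again adjusted over the list alone. GO terms with 10 to 300 tested genes were tested with camera, and with Fisher's exact test among the called genes against the 13098 tested genes that carried a term.

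The genes named were set by a rule fixed in advance: Sfswap, the 12 genes with the largest log2 fold change in each direction among called genes with no overlap between the groups and a symbol that is not a provisional one such as Gm22200, and the 4 members of smallest p in each list. Not every gene this rule picked is printed, and other genes named were chosen after their values were seen. Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, other scalings, other variance settings, sample weights, the replicate number as a block, each sample left out in turn, an adjusted p of 0.1, and a minimum log2 fold change of 1. Chosen after seeing the data were limma's voom on the recovered reads, a fit to the same genes without voom, a fit without genes under 200 bp of exons, and the choroid plexus score as a covariate.

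The procedure was tested on simulated data. For 12274 genes, reads were drawn from the real means, library totals and within-group spread, with 200 genes changed. On log2(FPKM + 1), limma called 42% of the genes changed 1.5-fold, 64% at 2-fold, 90% at 3-fold and 84% at 4-fold, out of 50 genes at each size, none of them in the wrong direction. It also called 10 unchanged genes. With no gene changed it called 0 genes and voom called 0, and camera called 0 of 32 lists. Each gene was drawn independently of the others, so the simulated genes were not correlated. The 0 of 32 lists therefore does not bear on camera's calls in the real data, where the estimated correlation was 0.65 for the microglia list.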

Results

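The series compared gene expression in the hippocampus of mice given a control virus with that of mice given a virus that knocks down SFRS8 (Sfswap), an RNA-binding protein that regulates pre-mRNA splicing. Its title asks whether this factor acts on the splicing of synaptic genes and on memory. There were 3 samples in each group, measured as FPKM per gene. The libraries behind the values held 17241307, 18097344 and 17969534 reads in control samples 1 to 3, and 17731035, 16622948 and 17431535 in knockdown samples 1 to 3. Control samples correlated with one another at r = 0.976 to 0.980, knockdown samples at 0.957 to 0.968, and samples of different groups at 0.939 to 0.965, over the log2(FPKM + 1) of 14013 genes within these 6 samples. The first principal component held 44.8% of the variance and placed the 3 knockdown samples on one side of the 3 control samples.

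Sfswap itself was lower in all 3 knockdown samples. The gene (ENSMUSG00000029439, mm10 chromosome 5, 129501221 to 129571384, plus strand) had 16.7, 18.5 and 19.2 FPKM in the control samples and 9.79, 11.3 and 9.58 in the knockdown samples, which left 56.4% of the control mean. These values rest on 2300, 2680 and 2765 reads in the controls and 1388, 1507 and 1336 in the knockdown samples. The log2 fold change was −0.77 (SE 0.09), with an adjusted p of 0.0432 in limma, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 samples against 3 allow. Under the alternatives the adjusted p ran from 0.0238 to 0.221, and the call was lost in 11 of 21, among them 5 of the 6 that left out a sample, while the direction held in all.

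**Figure D1:**
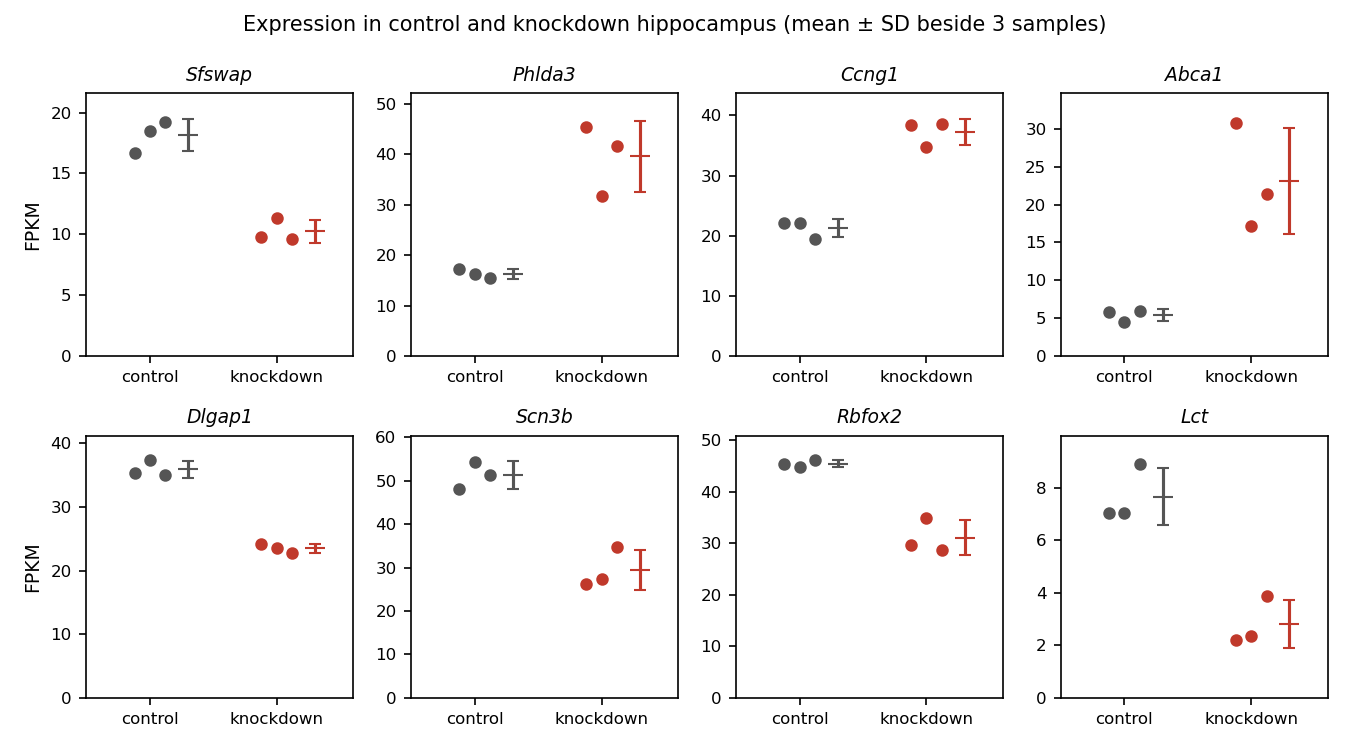
FPKM of 8 genes in each of the 3 control and 3 knockdown samples (points), with the mean ± SD beside them on a linear axis that starts at 0. Sfswap, Dlgap1, Scn3b, Rbfox2 and Lct lay lower in every knockdown sample than in any control sample, and Phlda3, Ccng1 and Abca1 lay higher.

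More genes were higher than lower in the knockdown hippocampus. Among the larger rises were those of Abca1, the cholesterol exporter, from 5.44 ± 0.797 to 23.1 ± 7.00 FPKM (SD, n = 3 in each group), of Mmp2, a matrix metalloproteinase, from 1.62 ± 0.344 to 7.34 ± 2.08, of Thbs4, a secreted thrombospondin, at 3.62-fold (adjusted p = 0.0452), and of Serping1, the inhibitor of complement C1, from 7.35 ± 2.20 to 23.2 ± 6.36. Ramp3, Creb3l1, Sdc1, Mamdc2, Cox6b2, A2m and Igsf1 also rose, by 3.13-fold to 7.14-fold. The immunoglobulin kappa segment Igkv1-110 rose most, from 0.798 ± 0.230 to 17.5 ± 8.10 FPKM, a value that is uncertain because the near-identical segments of this family share reads. Among the genes that fell, Lct, whose transcript marks dentate granule cells, fell to 0.368 of the control mean (log2 fold change −1.20), and Rasgrf2, an exchange factor for Ras, from 10.1 ± 0.453 to 5.17 ± 0.402.

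Scn3b, a beta subunit of voltage-gated sodium channels, fell to 0.574 of the control mean, Cdh24, a cadherin, to 0.478, Slc6a15, a transporter of neutral amino acids, to 0.553, and Rasd2, a small GTPase, to 0.631. Wscd2, Lzts3, Phyhip and Ube2ql1 fell to between 0.518 and 0.647 of the control means. Mir421 was also called lower, at 0.425 of the control mean, but its 76 bp are shorter than the selected fragments, so the value is no measure of the mature microRNA. The same holds for the largest fall, that of the small nucleolar RNA gene Gm22200 (67 bp), at 0.230 of the control mean.

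In all, limma called 168 genes higher and 32 lower among the 14013 tested, at ratios of 1.33 to 21.9 for the higher genes and 0.230 to 0.746 for the lower ones. All 200 had groups that did not overlap, as had 29.9% of the genes tested, where chance gives 10%. At an unadjusted p under 0.05 there were 2199 higher and 1118 lower genes. All 200 adjusted p-values lay between 0.0432 and 0.0490, and the counts moved strongly with the settings: they were 0 and 0 with no filter, after quantile normalization, without the variance trend and with the choroid plexus score as a covariate, and 498 and 96 with voom on the recovered reads. Leaving out control sample 1, control sample 2 or knockdown sample 1 gave 0 and 0, leaving out control sample 3 gave 8 and 0, and leaving out knockdown sample 3 gave 16 and 7. Scaling each sample to the same FPKM sum gave 30 and 5.

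In the p53 and DNA damage response list 5 genes rose. Phlda3 went from 16.3 ± 0.903 to 39.6 ± 7.03 FPKM, Ccng1 from 21.3 ± 1.52 to 37.2 ± 2.20, Trp53inp1 from 3.27 ± 0.865 to 8.13 ± 0.772, and Aen, a nuclease induced by p53, from 4.46 ± 0.123 to 7.23 ± 0.460. Bbc3, which encodes the pro-apoptotic protein PUMA, was the fifth called member, at 2.77-fold. Of 16 measured members, 5 were called higher over all genes tested and 11 were higher adjusted over the list alone, none lower. Cdkn1a stood at 2.15-fold with an adjusted p of 0.0744, and Mdm2 at 1.07-fold and Zmat3 at 0.959-fold did not pass either. The list's median log2 fold change was 0.56, its score was above every control in all 3 knockdown samples, and camera gave an adjusted p of 3.95e-07 (adjusted p = 0.245 with an estimated correlation), with 0.00769 by fry.

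Markers of microglia, phagocytes and antigen presentation were also higher. All 20 measured microglia markers had positive log2 fold changes, with a median of 0.55, and Tmem119 stood at 20.3 ± 2.71 against 14.0 ± 0.765 FPKM. None of the 20 was called over all genes tested and 12 were higher adjusted over the list alone (camera adjusted p = 3.95e-07, and adjusted p = 0.396 with an estimated correlation). The activated microglia and phagocyte list, which holds Tlr2, Axl, Cybb and Apoe, had a median of 0.85, with 0 of 20 members called and 13 higher adjusted over the list alone (camera adjusted p = 6.43e-07, and adjusted p = 0.396 with an estimated correlation). Knockdown sample 1 stood apart in both lists, with scores of 0.87 for microglia and 1.40 for activated microglia against 0.39 and 0.56 in knockdown sample 2 and 0.38 and 0.53 in knockdown sample 3. Without it the activated list had a median of 0.54. The Apoe value of that list was 2088 ± 589 against 1210 ± 112 FPKM. The antigen presentation and lymphocyte list had a median of 0.71, with H2-K1 at 101 ± 28.1 against 46.3 ± 17.7 FPKM, 0 of 18 members called and 10 higher adjusted over the list alone (camera adjusted p = 3.51e-06, and adjusted p = 0.419 with an estimated correlation). Its score was 0.50 in knockdown sample 3 and 0.62 in control sample 2, so the groups overlapped. H2 genes are a family whose members share reads. The interferon response list had a median of 0.31, with Trim30a at 1.79-fold and 0 of 29 members called either over all genes tested or adjusted over the list alone (camera adjusted p = 0.0197, and adjusted p = 0.693 with an estimated correlation). Its camera call ended without control sample 1 (median 0.17, adjusted p = 0.243), knockdown sample 1 (0.24, 0.0957) or knockdown sample 3 (0.11, 0.582), and without knockdown sample 2 the median was 0.53.

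Astrocyte genes moved in part. Aqp4, the water channel of astrocyte endfeet, rose from 36.4 ± 3.91 to 96.2 ± 31.8 FPKM, and Gja1, which encodes connexin 43, from 21.2 ± 2.12 to 36.0 ± 3.33, whereas Ntsr2 stood at 0.702-fold with an adjusted p of 0.0677. Of 17 astrocyte markers 2 were called higher, and adjusted over the list alone 2 were higher and 1 lower, with a median of 0.11 and a camera adjusted p of 0.155 (0.0401 without knockdown sample 3). In the reactive astrocyte list, Serping1 and Tm4sf1 were called, Cd44 stood at 2.40-fold and S1pr3 at 2.95-fold, and 10 of 18 members were higher adjusted over the list alone, with a median of 0.53 (camera adjusted p = 3.41e-05, and adjusted p = 0.245 with an estimated correlation). All 12 oligodendrocyte precursor markers had positive log2 fold changes with a median of 0.27, among them Gpr17 at 1.50-fold, with 0 called and 3 higher adjusted over the list alone (camera adjusted p = 0.00410, adjusted p = 0.245 with an estimated correlation, and 0.00611 by fry). The camera call was lost with a filter at 5 FPKM (0.0506). The oligodendrocyte and myelin list had a median of 0.22, with Cryab at 1.35-fold and 0 of 17 members called either over all genes tested or adjusted over the list alone (camera adjusted p = 0.00494, and adjusted p = 0.529 with an estimated correlation). Its call ended without control sample 3 (adjusted p = 0.0972) or knockdown sample 2 (0.135).

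Vessel markers had higher values, and transcripts of neighbouring tissue differed between samples. Pecam1, an adhesion protein of endothelium, rose from 3.02 ± 0.227 to 5.25 ± 0.463 FPKM, and Cdh5 and Rgs5 stood at 1.90-fold and 1.71-fold but did not pass over all genes tested. All 23 markers of endothelium, mural cells and fibroblasts had positive log2 fold changes with a median of 0.66, and 1 was called and 11 were higher adjusted over the list alone (camera adjusted p = 3.77e-07, adjusted p = 0.245 with an estimated correlation, and 0.0246 by fry). Ttr, the most abundant transcript of the choroid plexus, stood at 43.2, 60.2 and 2983 FPKM in control samples 1 to 3 and at 4523, 4208 and 1151 in knockdown samples 1 to 3. The choroid plexus and ependyma list had a median of 1.50, with 0 of 17 members called and 2, Rsph1 and Foxj1, higher adjusted over the list alone (camera adjusted p = 1.58e-05, and adjusted p = 0.419 with an estimated correlation). Its mean score relative to the control mean was −0.80, −0.54 and 1.34 in the controls and 1.85, 1.87 and 0.81 in the knockdown samples, so the groups overlapped. The median was 2.32 without control sample 3 and 0.998 without control sample 1.

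Markers of thalamus, cortex and striatum differed in both directions. Ramp3, a receptor partner expressed in thalamus, rose from 2.42 ± 0.728 to 11.5 ± 4.17 FPKM, Drd1, the dopamine D1 receptor of striatum, rose from 0.783 ± 0.127 to 2.44 ± 0.510, and Rasgrf2, listed as a cortical marker, fell. The thalamic marker Prkcd stood at 24.7 ± 9.53 against 8.10 ± 2.00 FPKM, with an adjusted p of 0.0568. Of 17 members 2 were called higher and 1 lower, and adjusted over the list alone 7 were higher and 1 lower, with a median of 0.58 (camera adjusted p = 0.00454, and adjusted p = 0.245 with an estimated correlation). That call was lost with a filter at 5 FPKM (median 0.92, adjusted p = 0.0888), with voom (0.51, 0.0550) and in the same genes without voom (0.38, 0.0569). In the blood list only Hba-a1 and Hbb-bs reached 1 FPKM, at 0.801-fold and 1.04-fold, so no list test was made. The sex-linked list had a median of 0.00 over 4 genes with 0 called and 0 adjusted over the list alone, and Ddx3y stood at 1.02-fold.

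**Figure D2:**
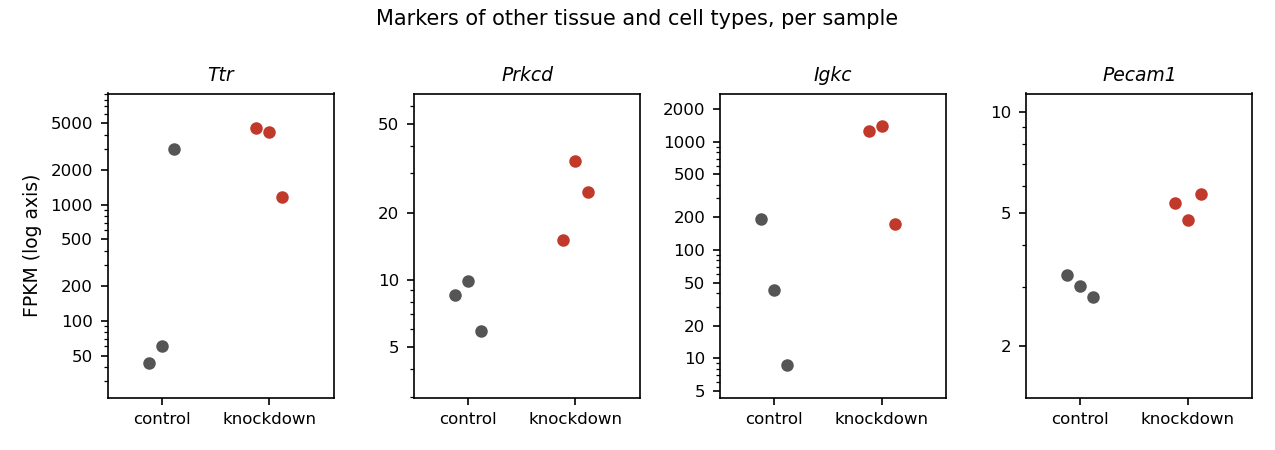
FPKM of 4 markers in each of the 3 control and 3 knockdown samples, on log axes: Ttr of choroid plexus, Prkcd of thalamus, Igkc of antibody-producing cells and Pecam1 of endothelium. Ttr in control sample 3 (2983) lay among the knockdown samples, and Igkc in knockdown sample 3 (172) lay under control sample 1 (196).

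Splicing factor transcripts other than Sfswap were slightly lower as groups. Of 36 SR proteins and their kinases, 35 had negative log2 fold changes, with a median of −0.12, and Sugp2 stood at 7.05 ± 0.0829 against 9.06 ± 0.232 FPKM and Srrm2 at 52.8 ± 5.95 against 65.5 ± 4.95. None was called, and 0 passed adjusted over the list alone (camera adjusted p = 4.47e-06, and adjusted p = 0.245 with an estimated correlation). Among 40 neuronal splicing regulators and hnRNPs, Rbfox2 fell from 45.5 ± 0.715 to 31.1 ± 3.33 FPKM and was the only member called, 2 were lower adjusted over the list alone, Celf4 stood at 0.700-fold and Qk at 1.37-fold, and the median was −0.14 (camera adjusted p = 4.49e-05, and adjusted p = 0.245 with an estimated correlation). The core spliceosome list had a median of −0.07 over 40 genes, with Snrpd3 at 0.832-fold, 0 called and 0 adjusted over the list alone (camera adjusted p = 0.00961, adjusted p = 0.245 with an estimated correlation, and 0.0246 by fry). Its camera call was lost with a filter at 5 FPKM (0.0526). Which exons of any gene were spliced in or out was not analysed here, since the values are per gene.

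Dlgap1, a scaffold protein of the postsynaptic density, fell from 35.9 ± 1.33 to 23.5 ± 0.674 FPKM, and was the only member of the 4 synaptic lists called. In the presynaptic vesicle and active zone list 31 of 37 members had negative log2 fold changes, with a median of −0.23, Nsf at 85.0 ± 14.1 against 130 ± 7.78 FPKM and Dnm1 at 219 ± 7.84 against 288 ± 21.6. None of the 37 was called and 10 were lower adjusted over the list alone (camera adjusted p = 6.43e-07, adjusted p = 0.245 with an estimated correlation, and 0.0564 by fry). The microglia list was higher in each of the samples in which this list was lower. Of 35 postsynaptic scaffold genes 1 was called and 2 were lower adjusted over the list alone, with Nrgn at 0.635-fold and a median of −0.13 (camera adjusted p = 0.00297, adjusted p = 0.419 with an estimated correlation, and 0.167 by fry). Without knockdown sample 2 that call ended and the median was −0.04 (adjusted p = 0.123).

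Channels and signalling genes held members that went both ways. Of 35 voltage-gated ion channels, Scn3b was called lower, and adjusted over the list alone 4 were lower and 1 higher, with Cacna1b at 0.709-fold and a median of −0.09 (camera adjusted p = 0.00354, and adjusted p = 0.245 with an estimated correlation). That median was −0.04 without control sample 1 or knockdown sample 2 and −0.05 without knockdown sample 1. Over 21 alternatives it ran from −0.16 to −0.02, and the camera call at the preset correlation held in each. Among 31 LTP and CREB signalling genes, Plcb1, a phospholipase, was called lower (14.7 ± 1.41 to 9.73 ± 0.695 FPKM), and adjusted over the list alone 6 were lower and 1 higher, with Map2k1 at 0.671-fold and Crtc1 at 0.726-fold (median −0.05, camera adjusted p = 0.0107, adjusted p = 0.245 with an estimated correlation, and 0.0246 by fry). The camera call was lost with a filter at 5 FPKM (0.0586) and after quantile normalization (0.0667), and the median was −0.09 without knockdown sample 2. Glutamate receptors had a median of −0.06 over 28 genes, with 0 called, 1 lower adjusted over the list alone, Gria1 at 0.749-fold and Grin2d at 1.53-fold (camera adjusted p = 0.163). GABA synapse genes had a median of −0.05 over 20 genes, with 0 called, 0 adjusted over the list alone and Gabrd at 1.41-fold (camera adjusted p = 0.284). The median of either of these lists changed sign under some alternatives.

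Markers of hippocampal neuron types were lowest for the dentate gyrus. Lct was called, Calb1 stood at 12.6 ± 5.19 against 24.4 ± 3.05 FPKM and Plk5 at 5.08 ± 2.32 against 9.91 ± 1.48. Of 17 dentate granule cell markers 15 had negative log2 fold changes, 1 was called and 5 were lower adjusted over the list alone, with a median of −0.28 (camera adjusted p = 1.24e-04, and adjusted p = 0.304 with an estimated correlation). Of 12 CA3 and mossy cell markers, Cdh24 was called lower, Coch stood at 2.33-fold, and adjusted over the list alone 1 was lower and 1 higher (median −0.20, camera adjusted p = 0.0382, and adjusted p = 0.436 with an estimated correlation). That call ended without control sample 2 (adjusted p = 0.0907), control sample 3 (0.0577) or knockdown sample 1 (0.567), where the median was −0.03. The score was −0.61 in knockdown sample 1, −0.01 in sample 2 and 0.08 in sample 3, so a single sample carried the value. Without knockdown sample 2 or 3 the median was −0.34 or −0.36. Of 18 interneuron markers 0 were called and 0 passed adjusted over the list alone, with Sst at 0.671-fold and Cck at 0.726-fold (median −0.12, camera adjusted p = 0.0221, and adjusted p = 0.529 with an estimated correlation). Without knockdown sample 3 the call ended and the median was 0.02 (adjusted p = 0.279). It was −0.07 and −0.22 without control samples 2 and 3, and −0.27 and −0.19 without knockdown samples 1 and 2. CA1 pyramidal markers had a median of −0.20 over 11 genes, with 0 called and, adjusted over the list alone, 2 lower and 1 higher, Lefty1 at 0.594-fold and Man1a at 1.41-fold (camera adjusted p = 0.179). Without knockdown sample 1 this list passed (0.00485).

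Stress, activity and housekeeping lists did not pass with all 6 samples and the settings used here. In the unfolded protein and integrated stress response list the endoplasmic reticulum chaperones Pdia4, Sdf2l1 and Manf stood at 1.64-fold, 1.85-fold and 1.52-fold, with 0 of 19 members called, 7 higher and 3 lower adjusted over the list alone, and a median of 0.23 (camera adjusted p = 0.132). In the heat shock list Bag3, a co-chaperone, rose 1.93-fold as the only called member, Hspb1 stood at 2.29-fold, and 2 of 15 were higher adjusted over the list alone (median 0.10, camera adjusted p = 0.135). Of 27 immediate early genes only Sik1, a kinase gene, was called, at 1.95-fold, with 1 higher adjusted over the list alone, and Egr3 stood at 0.765-fold (median 0.08, camera adjusted p = 0.481). Neither cytosolic ribosomal proteins (48 genes, median 0.07, camera adjusted p = 0.273), nuclear-encoded oxidative phosphorylation (57 genes, median −0.01, camera adjusted p = 0.316) nor mitochondrially encoded genes (13 genes, median −0.06, camera adjusted p = 0.273) had a member called, with 0 adjusted over the list alone in each. Some of these lists passed when a sample was left out: unfolded protein without control sample 3 (0.0282), heat shock without knockdown sample 1 (0.00313), ribosomal without control sample 1 (0.0457) or knockdown sample 3 (0.00119), oxidative phosphorylation without control sample 2 (0.0235), and mitochondrially encoded without control sample 3 (0.0319) or knockdown sample 2 (0.0287). For the sex-linked list camera gave an adjusted p of 0.671.

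**Figure D3:**
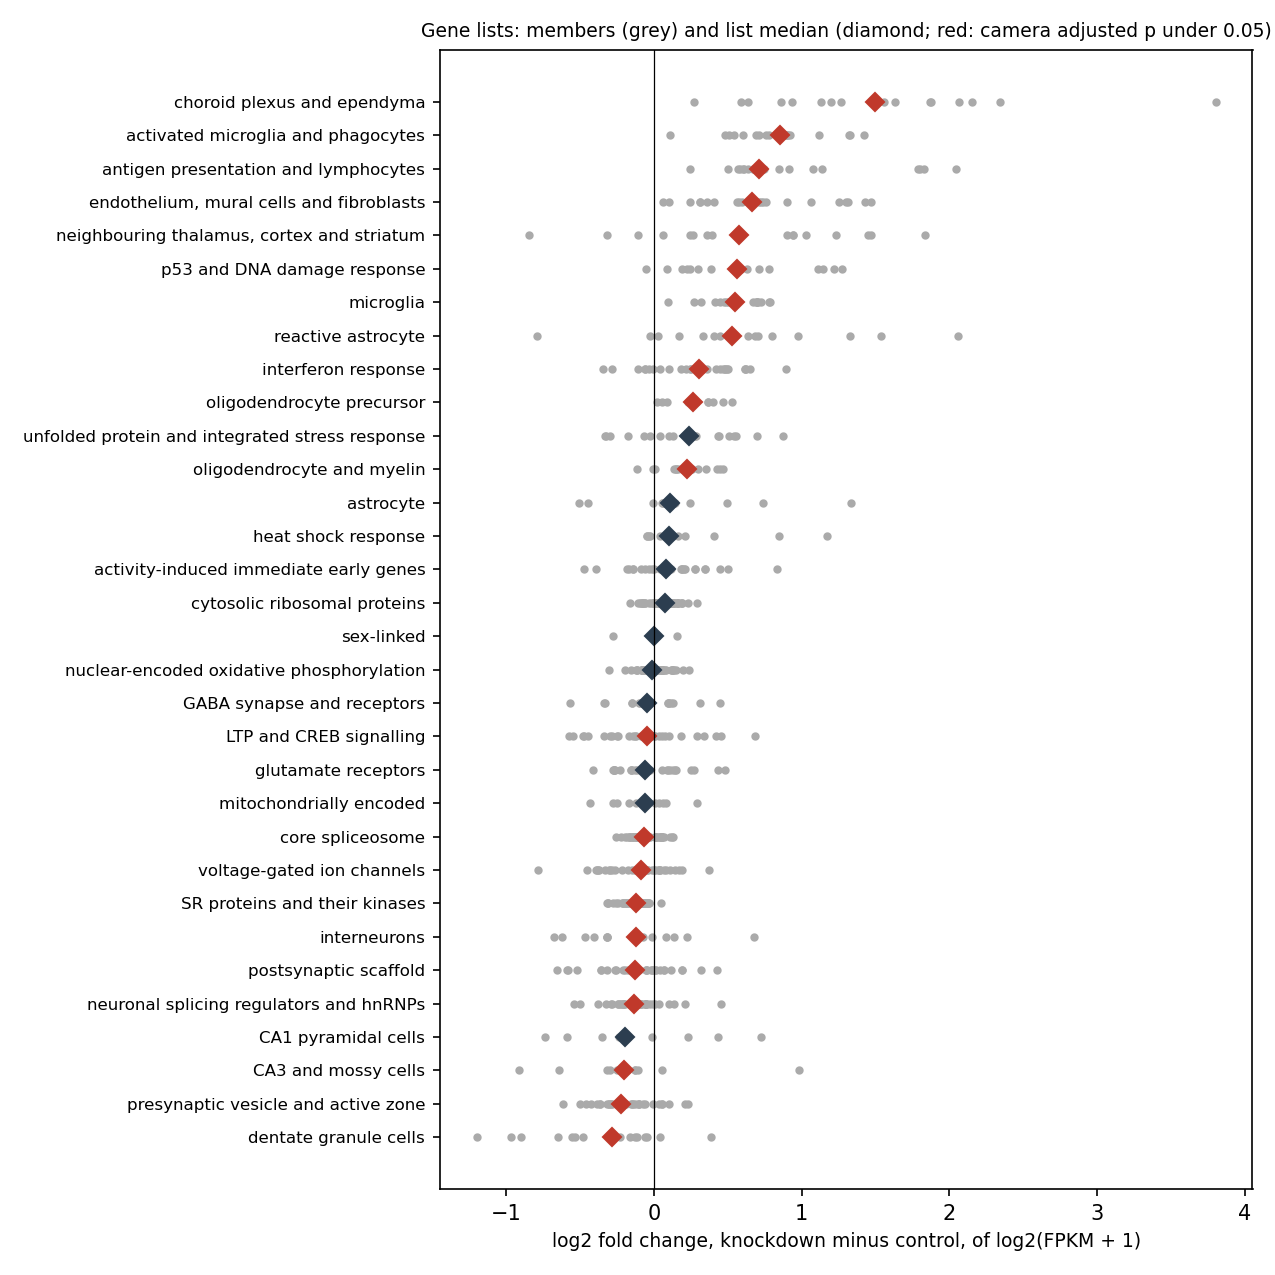
Log2 fold change, knockdown minus control on the log2(FPKM + 1) scale, of the members (grey points) and the median (diamonds) of the 32 gene lists tested, with red diamonds where camera's adjusted p at the preset correlation was under 0.05. Medians ran from −0.28 for dentate granule cells to 1.50 for choroid plexus and ependyma, and no list passed with an estimated correlation.

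Across the 32 lists camera called 11 higher and 10 lower at the preset correlation, and 0 and 0 with an estimated correlation. By fry, whose p-value tests only whether members move on balance one way, the p53, oligodendrocyte precursor, vessel, core spliceosome and LTP lists had adjusted p-values under 0.05. Among the GO terms that the table carries, camera called 207 higher and 23 lower of 2534, and 0 of either with an estimated correlation. The higher terms were led by external side of plasma membrane (142 genes, median 0.47, adjusted p = 2.03e-08, adjusted p = 0.567 with an estimated correlation), defense response to bacterium (46 genes, median 0.73) and basement membrane (63 genes, median 0.41). Antigen binding (83 genes, median 1.51) and immunoglobulin receptor binding (16 genes, median 2.09) were also called higher, and 81 tested genes were immunoglobulin segments. How far these segments carry the higher terms was not tested. The lower ones included mRNA processing (196 genes, median −0.07, adjusted p = 0.00352), RNA splicing (157 genes, median −0.07, adjusted p = 0.00516, with 0.572 as the adjusted p with an estimated correlation for both) and terminal bouton (49 genes, median −0.13). Among called higher genes, Fisher's exact test passed for 4 terms, with external side of plasma membrane at 14 genes where 1.77 were expected and positive regulation of cholesterol efflux at 4 where 0.137 were expected, and for 0 terms among the called lower genes.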

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

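The voom fit, the fit to the same genes without voom, the fit without short genes and the choroid plexus covariate were chosen after seeing the data. The counts of calls moved with the processing, and the adjusted p-values of all 200 called genes lay just under the threshold. All of those genes that were tested kept their direction and an unadjusted p under 0.05 in every alternative. Why the counts moved was not tested. Genes higher and lower in knockdown, 168 and 32 as reported, numbered 290 and 64 at a pseudocount of 0.1, 274 and 64 at 0.5, 170 and 65 with a filter at 5 FPKM, 318 and 72 with robust variances, 498 and 96 with voom on the recovered reads, 983 and 352 at an adjusted p under 0.1, and 37 and 3 at an absolute log2 fold change of at least 1. They numbered 30 and 5 when each sample was scaled to the same FPKM sum, 100 and 26 with median-ratio scaling, 103 and 34 without short genes, and 106 and 20 in the same genes as the voom fit. Of the FPKM sum, the gene Gm23935 alone held 1.81% in control sample 2 and 11.0% in control sample 1, its lowest and highest shares. With no filter (4416 genes at an unadjusted p under 0.05), quantile normalization (3431), no variance trend (3288) or the choroid plexus score as a covariate (1817), limma called 0 higher and 0 lower genes. Leaving out each sample in turn gave 0 to 160 higher and 0 to 30 lower genes.

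Sfswap kept its direction in all alternatives, with an adjusted p of 0.0238 to 0.221, and lost its call in 11 of 21. Its log2 fold change there was −0.77 with no filter and without the variance trend, −0.83 with samples scaled to the same FPKM sum, −0.80 after quantile normalization, −0.89 with the choroid plexus covariate, and −0.84 to −0.73 when each sample was left out in turn. With the replicate block, in which the replicate number was an added term, Sfswap stood at −0.77 (adjusted p = 0.0821) and limma called 0 higher and 0 lower genes, with 3037 at an unadjusted p under 0.05. The deviations of same-numbered samples from their group means correlated at 0.05, 0.04 and −0.01. These values give no sign that the numbers pair the samples, but cannot exclude a pairing that affects some genes.

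Camera called 0 lists higher and 0 lower with an estimated correlation, and 0 GO terms higher and 0 lower. Of the list medians under the other alternatives, 627 stayed on their side of the threshold, 26 lost and 16 gained a call (unfolded protein and ribosomal 3 each, astrocyte, CA1, heat shock, oxidative phosphorylation and mitochondrially encoded 2 each), and 2 called medians were reversed: the choroid plexus list stood at −0.10 with its own score as covariate, and the interneuron list at 0.0196 without knockdown sample 3, in a range of −0.27 to 0.0196 when each sample was left out in turn. Uncalled values also changed sign, 17 of lists and 17 of genes, all counted as unchanged. Of the named genes' values 2519 stayed on their side, 425 lost and 93 gained a call, and 0 called ones were reversed. The CA3, interneuron, thalamus and interferon lists lost their call in 10, 3, 3 and 4 of the alternatives, and the LTP and core spliceosome lists in 2 and 1. The p53, microglia, vessel, presynaptic, SR protein and dentate lists kept theirs in 21 of 21. The alternative planned for deposited counts was not run, because the table holds none, and voom was fitted to the recovered reads instead. Depth limits genes with few reads, since 1 read on a gene of 1 kb was worth up to 0.0602 FPKM.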

Other observations

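All tests in this part were chosen only after the result was seen, except the count of splits and the tests of the LXR target and sterol lists. Those lists were drawn up after the calls were seen and were tested on members not singled out before. They are not independent of the earlier tests, since members such as Abca7 and Hmgcs1 also belong to GO terms that camera called at the preset correlation.

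Antibody transcripts differed widely between samples. The FPKM of 177 immunoglobulin gene segments summed to 738, 171 and 37.1 in control samples 1 to 3 and to 4640, 5896 and 583 in knockdown samples 1 to 3. The kappa constant gene Igkc reached 1269 and 1401 FPKM in knockdown samples 1 and 2, 172 in knockdown sample 3 and 196 in control sample 1, so the groups overlapped. The abundant variable segments differed between samples: Igkv14-111 stood at 1117 FPKM in knockdown sample 2 and 1.69 in knockdown sample 1, and Igkv4-53 at 519 in knockdown sample 1 and 3.61 in knockdown sample 2. Segments of this family share reads, so single-segment values are uncertain.

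Called genes of cholesterol export and sterol regulation went in opposite directions. Called higher were Abca1, Abcg1 (26.2 against 17.3 FPKM), Pltp (35.5 against 15.9) and Nr1h3, which encodes the oxysterol receptor LXR alpha (3.99 against 1.72), and Srebf2, which encodes the master regulator of sterol synthesis, was called lower (40.9 against 54.8). A candidate explanation is that LXR targets rose as a group: the 10 members not singled out before, among them Lpcat3, Mylip and Abca7, all had positive log2 fold changes with a median of 0.37 (camera p = 7.08e-04, p = 0.0742 with an estimated correlation, fry p = 0.00746). Sterol synthesis and uptake genes other than Srebf2, such as Fdft1 and Mvk, had a median of −0.23, and 20 of 22 did not have a positive value (camera p = 7.80e-05, p = 0.257 with an estimated correlation, fry p = 0.114). Both results are hypotheses about the same samples, and cell types that carry these genes in other proportions may contribute.

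Of the 10 splits of the 6 samples into 3 and 3, 1 gave as many genes past the threshold as the real split, namely the real split itself with 200, and the highest of the others gave 0. Splits of this number are too few for a share under 0.05.

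The p53 list was higher in all 3 knockdown samples. Choroid plexus tissue in the samples is argued against as its whole cause, since with the choroid plexus score in the model the list's score still differed by 0.68 between the groups over the 6 samples (SE 0.09), with a 95% interval above 0. More microglia stays open. The list's median lay only 0.0161 above the microglia median (SE 0.114 over list members, not over samples), which cannot decide the question. In knockdown samples 1 to 3 the p53 score was 0.63, 0.50 and 0.63, and the microglia score was 0.87, 0.39 and 0.38. So few samples cannot show whether one list follows the other. An effect of the knockdown and one of the virus dose or vector, on which no label gives a value, could not be separated here.

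The microglia and vessel lists were higher in all 3 knockdown samples, and the antigen list on average. Blood left in the tissue is argued against for the antigen list, since the summed haemoglobin and Alas2 FPKM, which blood would bring in abundance, differed by −0.356 between the groups (SE 1.02, upper 95% bound 2.47), where the list's summed FPKM stood at least 230 above the control mean in each knockdown sample. That haemoglobin sum was only 3.61 to 6.69 FPKM over the 6 samples. If reads shared between similar haemoglobin genes were dropped in counting, which is not recorded, it would understate blood. With the choroid plexus score in the model the microglia difference grew from 0.55 to 0.63 (SE 0.29). The antigen presentation difference grew from 0.96 to 1.05 (SE 0.68), and the vessel difference stayed at 0.72 (SE 0.32). The fitted slopes on the choroid plexus score were −0.057 for microglia, −0.057 for antigen presentation and 0.0014 for vessels. None of these lists thus rose clearly with that score within the groups, though slopes over 6 samples are uncertain. Camera's calls held at the preset correlation, but without that score they were already lost with an estimated correlation. Whether choroid plexus tissue is the whole cause cannot be told from this, since each 95% interval over the 6 samples includes 0. An immune reaction to the virus or its product and a response to lower Sfswap may each contribute and were not tested.

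The presynaptic list was lower in all 3 knockdown samples. A lower share of neurons stays open. Were it the only change, the markers of other cell types would rise alike. The microglia score minus the astrocyte score differed by 0.38 between the groups, with an SE of 0.17 and a 95% interval that includes 0, and by 0.22 (SE 0.09) without knockdown sample 1. This contrast cannot decide the question, since it takes a single pair of lists and those cells may change in other ways too. With the choroid plexus score in the model the difference went from −0.19 to −0.15 (SE 0.08), with a 95% interval that includes 0. Camera's call held at the preset correlation, but without that score it was already lost with an estimated correlation. Whether choroid plexus tissue is the whole cause of this fall cannot be told here. Neighbouring thalamus in the dissected tissue cannot be told apart from the group, since the mean score of 7 thalamic markers was 1.19 higher in knockdown (SE 0.32) and higher in each knockdown sample than in any control. The same limit holds for the splicing factor and dentate granule cell lists, whose scores were lower in each knockdown sample than in any control. It also holds for the p53, microglia and vessel lists, whose scores were higher in each knockdown sample than in any control.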
